A study of Mus musculus with 2 samples.

How the data were processed

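H3K9me3 ChIP-seq peaks of hindbrain from mouse embryos of strain B6NTac;B6NCrl/Lap at 14.5 days were analysed. Replicate 1 came from 24 embryos and replicate 2 from 34, with the sexes pooled and 3 technical replicates together in each. Each replicate's list, a list from the pooled reads of both and a list of replicated peaks were used. All are narrowPeak lists on mm10, made by the authors with control reads. The signal values are the authors' enrichment measure per peak, never negative, and whether they are a linear fold over the control is not given in the sources used here. The deposited −log10 p and −log10 q values come from the authors' peak caller. The deposited display score and the −log10 p were not used in any test, and the deposited summit offset is a distance in bp. Aligner, peak caller, thresholds and the rule behind the replicated list are not given in the sources used here. Read counts were not used here, so the sequencing depth is unknown, and a gene without a peak had no enrichment that the authors' caller detected, which does not exclude a weaker one.

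The replicated list was the main list. Genes came from GENCODE M21 and sequence and soft-masking from GRCm38, the same assembly as mm10. Tests used chromosomes 1 to 19, X and Y. Peaks on other contigs were counted apart. Overlapping peaks within a list were merged before base pairs were counted. A gene carried a peak when its body overlapped one by at least 1 bp, and a promoter was the transcription start site ± 1 kb. The 19 gene lists were C2H2 zinc finger genes (Zfp, Zscan and Zkscan symbols), Zbtb genes, clustered protocadherins, olfactory receptors, vomeronasal receptors, Hox genes, imprinted genes, germline genes, hindbrain and neural progenitor transcription factors, neuronal, glial, ribosomal protein, replication-dependent histone, erythroid, microglial and immune, endothelial and meningeal, and liver and muscle lineage genes, keratins, and other tandem clusters (Cyp, Ugt, Serpin, Klk, Defb, Mup, Scgb and Krtap). The symbols Hbb-b1, Hbb-b2 and Ahsp matched no gene.

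Tests were two-sided rotation permutation tests. All peaks of a chromosome were shifted together by a random offset along its sequence with assembly gaps removed, which keeps widths, spacing and the clustering of genes. The p was doubled from the smaller tail and adjusted by Benjamini-Hochberg within each result. Gene lists, promoters and position within zinc finger genes had 100000 rotations, features and the overlap of replicates 10000, and sequence composition 1000. These p-values measure the placement of peaks along the genome, not variation between embryos. With 1 group of 2 samples no comparison between groups was possible, so replicate values are given beside many of the main values, though not all. Simulated peak lists with nothing planted were random rotations of the replicated list. In these, 2.84% of gene list tests, 2.16% of promoter tests, 5% of zinc finger position tests and 10% of feature tests (exons, 100 simulations) had a permutation p under 0.05. This checks how the p is computed, and cannot show whether rotation is a fair null. Peaks were planted in the 3′ part or at the transcription start site of 30% of the zinc finger genes, in 20 simulations each. The gene list and position tests recovered the former, and the promoter test the latter, in 100% of simulations.

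The genes named were those with the most base pairs in replicated peaks (10 genes), those whose promoters held the peaks of highest signal value (10 genes), the genes at the 5 widest and 5 highest-signal peaks, up to 4 members per list with the largest percent of the body covered, and a fixed set (Peg3, Snrpn, H19, Kcnq1ot1, Airn, Meg3, Hoxa9, Hoxb4, Sox2, Atoh1, Ptf1a, Dazl, Pcdhb4, Setdb1 and Trim28). The lists, the naming rule, the tests and most alternatives were chosen before the data were examined. These alternatives were each replicate's own list, the pooled list, the 50% of peaks of highest −log10 q, the autosomes, peaks without the 1% of highest signal value, at least 500 bp per gene, the gene plus 10 kb, promoters of 2.5 kb, other overlap rules, lists shortened to equal length, and random gene lists matched on length in 10 strata with 10000 draws. Random lists matched on soft-masked percent, and the replicated peaks found in both replicates' own lists, were added after the data were seen. Random lists draw genes singly, so unlike the rotations their p-values do not keep the clustering of genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9 were used.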

Results

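H3K9me3, a histone mark of silenced chromatin, was profiled by ChIP-seq in hindbrain dissected from mouse embryos at 14.5 days, in 2 biological replicates that pooled 24 and 34 embryos. Peak positions are given in mm10, values per replicate as mean ± SD over n = 2 replicates, and the other values come from the list of replicated peaks. In rotation permutation tests 2e-05 is the smallest p that 100000 rotations can give, and 0.00019 is that value after adjustment over the 19 gene lists.

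C2H2 zinc finger genes, clustered protocadherins, vomeronasal receptors, imprinted genes and germline genes carried more peaks than the same peaks rotated along the chromosomes. Peaks covered a mean of 46.9% of a protocadherin gene, 16.1% of an imprinted gene, 8.0% of a zinc finger gene and 4.70% of a vomeronasal receptor gene, against 1.03% of all 21911 protein-coding genes. No replicated peak lay in the 39 Hox genes, the 76 ribosomal protein genes, the 67 replication-dependent histone genes, the 53 keratins, the 22 microglial and immune genes or the 17 erythroid genes. Peaks of replicates 1 and 2 alone overlapped 1 and 6 Hox genes and 2 and 2 erythroid genes. Those of replicate 2 also overlapped 2 microglial and immune genes, 1 histone gene and 1 keratin. Of the C2H2 zinc finger genes, 164 of 417 overlapped a replicated peak, 2.24-fold the rotated mean of 73.2 ± 11.2 (SD over rotations; two-sided rotation permutation test, adjusted p = 0.00019). Imprinted genes had 32 of 41 (3.32-fold; permutation test, adjusted p = 0.00019), vomeronasal receptors 105 of 326 (2.45-fold; permutation test, adjusted p = 0.00038) and clustered protocadherins 52 of 56 (2.51-fold; permutation test, adjusted p = 0.00589). Germline genes had 15 of 37 (1.97-fold; permutation test, adjusted p = 0.0186), a call that ended in either replicate's own list, in the pooled list, on the autosomes alone, with at least 500 bp of overlap and with 10 kb added to the gene, with adjusted permutation p from 0.0758 to 0.394.

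**Figure D1:**
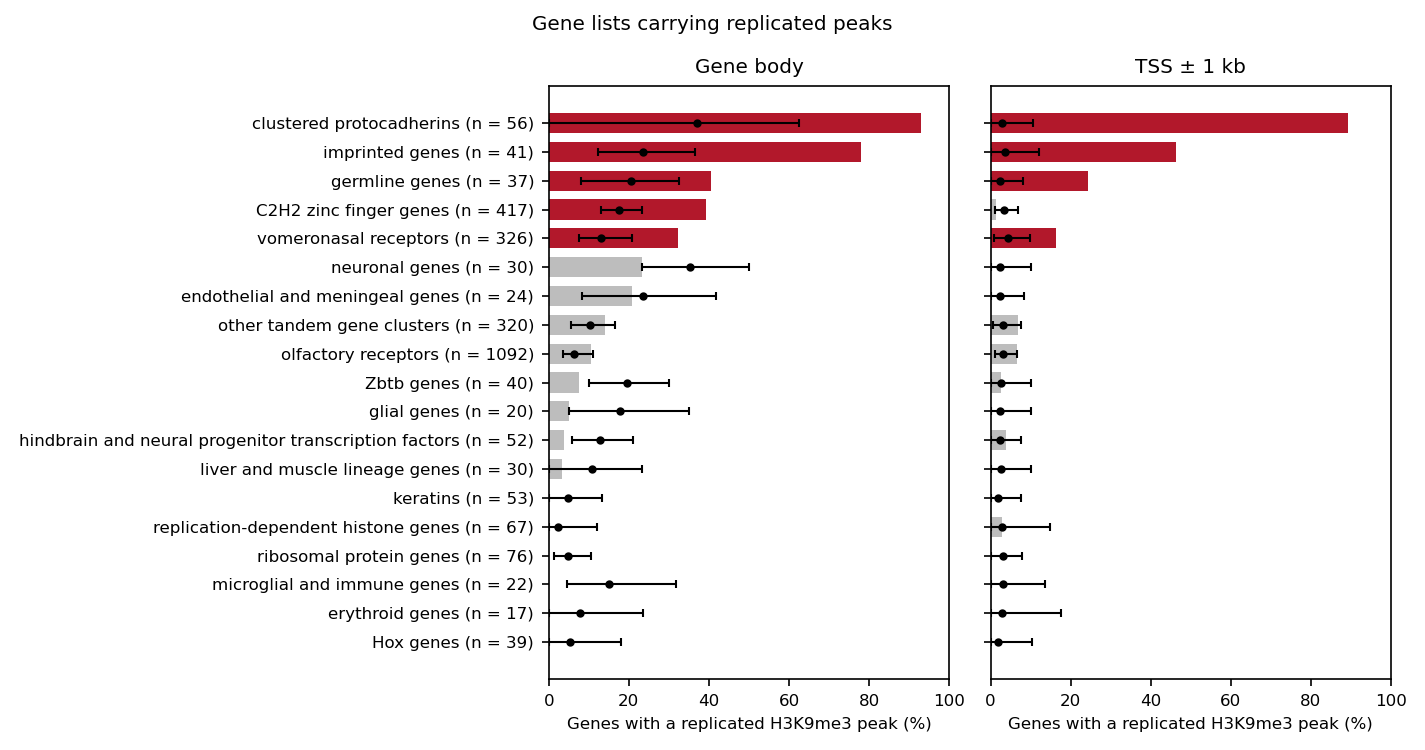
Percent of the genes of each list with a replicated H3K9me3 peak in the gene body (left) or within 1 kb of the transcription start site (right); bars in red passed an adjusted p of 0.05 in the rotation permutation test, and points with bars give the mean and the central 95% of the rotations. Clustered protocadherins reached 92.9% of gene bodies and 89.3% of promoters, and C2H2 zinc finger genes 39.3% of gene bodies and 1.44% of promoters.

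In the replicated list the other 14 lists did not pass the threshold in gene bodies. Olfactory receptors overlapped peaks in 115 of 1092 genes (1.66-fold; permutation test, adjusted p = 0.146) and other tandem clusters, such as Ugt and Scgb genes, in 45 of 320 (1.38-fold; permutation test, adjusted p = 0.289). The other tandem clusters passed in replicate 1's own list (1.65-fold; permutation test, adjusted p = 0.0447) and against random lists of genes of like length (1.84-fold; permutation test, adjusted p = 0.00109). For olfactory receptors the direction turned with the comparison. The fold was 2.12 over random lists of genes of like length and 0.717 against random lists of like repeat content. Both had an adjusted p of 0.00076 in tests on random gene draws. These draws take genes singly and ignore their clustering, so the p-values are too small for tandem families. The lists matched on repeat content were not matched on length. Both the 2 of 52 hindbrain and neural progenitor transcription factors and the 3 of 40 Zbtb genes lay below the rotated mean (0.300-fold and 0.383-fold), with an adjusted permutation p of 0.0844 for each. In all, 4 lists lay below the rotated mean at an unadjusted permutation p under 0.05 and none after adjustment, against 2 after adjustment in replicate 2's own list, 4 in replicate 1's and 4 in the pooled list. The counts were 7 of 30 neuronal genes, 5 of 24 endothelial and meningeal genes, 1 of 20 glial genes and 1 of 30 liver and muscle lineage genes. In the own lists of replicates 1 and 2 they were 15 and 14, 5 and 8, 0 and 4, and 3 and 3, in the same order. Adjusted permutation p was 0.0902 for the microglial and immune genes and 0.105 for the ribosomal protein genes, and for the remaining 8 lists without a call, the Hox, histone, keratin and erythroid lists among them, it ran from 0.247 to 0.976.

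Protocadherin, imprinted, germline and vomeronasal receptor genes also carried more peaks at their promoters than on rotation, and no such excess was detected for zinc finger genes. A replicated peak lay within 1 kb of the transcription start site of 50 of 56 protocadherins (32.5-fold; permutation test, adjusted p = 0.0019), 19 of 41 imprinted genes (12.5-fold; permutation test, adjusted p = 0.00019), 9 of 37 germline genes (10.4-fold; permutation test, adjusted p = 0.00019) and 53 of 326 vomeronasal receptors (3.82-fold; permutation test, adjusted p = 0.00127). The vomeronasal call ended among the 50% of peaks of highest −log10 q, where the adjusted permutation p was 0.12. Zinc finger gene promoters numbered 6 of 417 (0.419-fold; permutation test, adjusted p = 0.356), against 475 of all 21911 protein-coding genes. Olfactory receptor promoters numbered 73 of 1092 (2.20-fold; permutation test, adjusted p = 0.172) and passed the threshold in the pooled list with an adjusted permutation p of 0.0462. Among other tandem clusters 22 of 320 promoters carried a peak (2.16-fold; permutation test, adjusted p = 0.294). Both these clusters and olfactory receptors passed against random lists matched on length or repeat content, which ignore the clustering of genes. Promoter peaks were found for 2 hindbrain transcription factors, 2 histone genes and 1 Zbtb gene, and the 9 lists left, among them the Hox, neuronal and glial genes, had none.

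The clustered protocadherins on chromosome 18 formed the most heavily covered stretch of gene sequence. The 10 protein-coding genes with the most base pairs in replicated peaks were Gm42416, Gm37013, Gm37388, Pcdhga1, Pcdhga2, Pcdhga3, Pcdha1, Pcdhgb1, Pcdha2 and, outside this locus, Skint5 on chromosome 4. The annotated models of these protocadherins overlap each other and share the same peaks, so their values are not independent. Pcdhga1 had 59.1% of its 180081 bp in peaks (replicates 55.3% ± 2.55, n = 2), and the model Gm42416, which spans the locus, 42.1% of 887460 bp. The genes Pcdhb1 and Pcdhb2 lay fully inside replicated peaks, with 74.9% ± 12.5 and 71.3% ± 9.30 covered in the replicates (n = 2). Pcdhb22 had 87.3%, Pcdhb19 87.2% and Pcdhb4 70.1% of the gene body in peaks. Skint5 had 17.2% of 521613 bp in peaks.

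**Figure D2:**
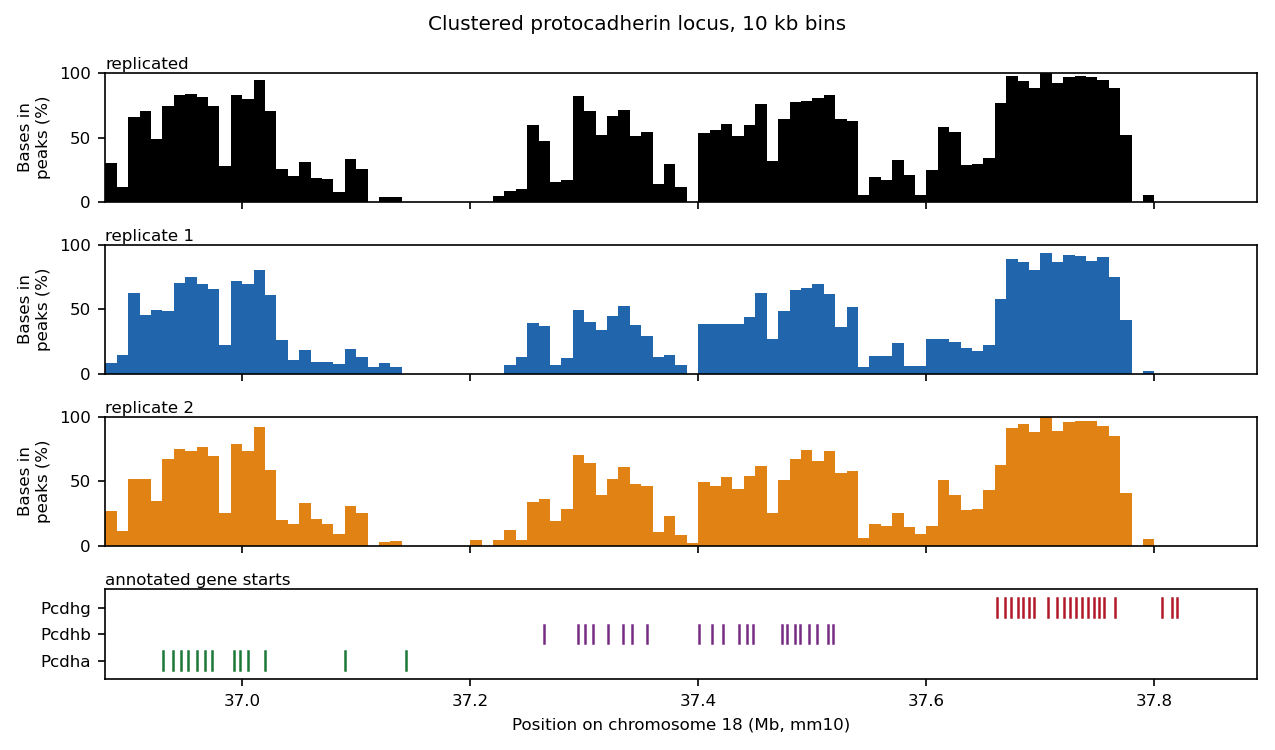
Percent of bases in H3K9me3 peaks in 10 kb bins along the clustered protocadherin locus of chromosome 18, for the replicated list and both replicates, above the annotated starts of the Pcdha, Pcdhb and Pcdhg genes. Peaks were densest over the Pcdhg gene starts, and the highest-signal peak there, with a signal value of 12.3, ran from 37744219 to 37750576.

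Klf14, an intronless gene on chromosome 6, lay inside the replicated peak of highest signal value on any chromosome. That peak ran from 30954906 to 30960469, a width of 5564 bp, with a signal value of 21.3, and Klf14 had 96.6% ± 4.84 of its body covered in the replicates (n = 2). The other promoters with the strongest replicated peaks were those of Pcdhga10 (signal value 12.3), Pcdha11, Pcdhga11, Pcdhgb7, Pcdha5, Pcdhgb6, Pcdha8 and Pcdhga8, and of Tcfl5 on chromosome 2 (10.1). Tcfl5 had 0.125% of its body in peaks. Of the 5 highest-signal peaks, 3 lay on contigs outside the assembled chromosomes. The widest replicated peak, 15360 bp on chromosome 1, started at 88236496 and overlapped Mroh2a. The fourth, of 11052 bp, also overlapped Mroh2a and ended just before it, at 88236445. Neighbouring peaks can thus be parts of 1 longer marked stretch. The others of the 5 widest overlapped Zfp933 (12006 bp), Gm37013 (11174 bp) and Zfp606 (10659 bp).

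Zinc finger genes were covered towards their 3′ end. Zfp873 on chromosome 10 had 92.2% of its gene body in replicated peaks (replicates 83.9% ± 8.28, n = 2), Zfp110 on chromosome 7 89.5% (84.9% ± 4.44), Zfp2 on chromosome 11 88.4% (73.8% ± 3.12) and Zfp68 on chromosome 5 85.2% (76.1% ± 6.98). Over all 417 zinc finger genes, peaks covered a mean of 12.1% of the gene's 3′ part and 3.86% of its 5′ part, split at the midpoint. The difference of 8.28 percentage points exceeded the rotated SD of 0.244 (two-sided rotation permutation test, p = 2e-05, the smallest that 100000 rotations can give), and it was 6.57 in replicate 1 and 7.56 in replicate 2. Coverage was higher in the 3′ part of 136 genes and in the 5′ part of 28. The last exon, which holds the zinc finger array in many of these genes, had 19.5% of its base pairs in peaks, the rest of the gene 3.97%, and 123 genes had a peak there. Zbtb genes, zinc finger genes of another family, had peaks in Zbtb38 (2.05% of the body), Zbtb7c (1.15%) and Zbtb20 (0.404%).

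**Figure D3:**
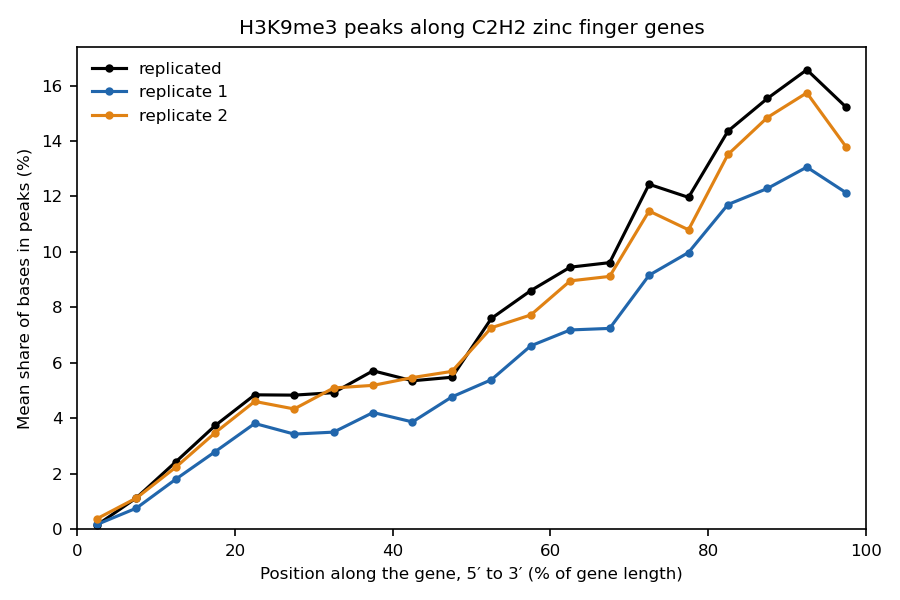
Mean percent of bases in H3K9me3 peaks in 20 bins from the 5′ to the 3′ end of 417 C2H2 zinc finger genes, for the replicated list and both replicates. Coverage in the replicated list rose from 0.143% in the first bin to 16.6% in the bin from 90 to 95% of the gene length.

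Imprinted genes differed widely in how much of the gene was covered. Nap1l5 had 94.6% of its body in replicated peaks, Nnat 92.0%, Cdkn1c 68.9% and the non-coding Peg13 63.3%, each with a peak at its promoter. In the replicates these values were 87.6% ± 12.8, 76.4% ± 1.27, 36.7% ± 3.99 and 48.4% ± 3.86 (n = 2). Peg3 had 13% (replicates 10.2% ± 2.62), Kcnq1ot1 7.76%, Snrpn 5.28%, Airn 4.07% and Meg3 3.20%, whereas H19 had no replicated peak. The sexes and parental alleles are pooled in these values. Of the germline genes named, Dazl had 3.39% of its body covered, Meioc 7.23%, Taf7l 4.80% and Rhox13 4.54%. In the replicates these values were 1.94% ± 0.576, 4.51% ± 3.52, 4.06% ± 1.06 and 4.49% ± 0.453 (n = 2). All of these genes but Meioc had a replicated promoter peak, and that of Taf7l was absent from replicate 1's own list.

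The olfactory receptor Olfr356 had 97.2% of its body in replicated peaks but 49.7% ± 35.4 in the replicates (n = 2), and the vomeronasal receptor Vmn1r65 had 67.6% and 43.5% ± 33.6. Olfr1453 had 67.2%, Olfr397 60.8% and Olfr355 56.3% in replicated peaks. The replicates gave lower values, with 27.5% for Olfr1453 in replicate 1 and 62.9% in replicate 2. Olfr397 and Olfr355 had 31.3% ± 6.27 and 23.4% ± 5.05 in the replicates (n = 2). Vmn1r66, Vmn1r70 and Vmn1r179 had 54.9%, 54.2% and 51.2% in replicated peaks, and 38.6% ± 1.99, 33.6% ± 10.9 and 23.6% ± 8.30 in the replicates. Ugt1a1 on chromosome 1 was covered over 97.4% of its body in the replicated list and 96.8% ± 0.362 in the replicates. The secretoglobin genes Scgb2b26, Scgb2b24 and Scgb2b21 on chromosome 7 had 88.4%, 85.5% and 82.9% in replicated peaks. In both replicates these values were lower, at 38.1%, 67.5% and 27.8% in replicate 1 and 47.8%, 65.4% and 75.7% in replicate 2.

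Sox2, Atoh1, Ptf1a, Hoxa9 and Hoxb4 had no peak in the replicated list or in either replicate. Hindbrain and neural progenitor transcription factors overlapped a peak in 4 of 52 genes in replicate 1 and 8 of 52 in replicate 2. In their list Tlx3 had 17.9% of its body covered (replicates 6.29% ± 8.89, n = 2), with a promoter peak of signal value 2.77, and Pax3 0.577%. Tlx3 had no peak in its body or promoter in replicate 2's own list. Trim28, which encodes a corepressor in the H3K9me3 pathway, had no peak, and the H3K9 methyltransferase gene Setdb1 had 1.39% of its body in peaks. The neuronal genes with most coverage were Nefm (8.77%), Chat (1.65%), Snap25 (1.44%) and Tph2 (0.933%). Chat had 0.455% in replicate 1 and 2.97% in replicate 2, and Tph2 0.335% and 1.25%. Foxc1 (5.54%), Pdgfrb (5.42%), Tek (0.584%) and Emcn (0.541%) led the endothelial and meningeal genes. Slc1a2 (0.241%) was the glial gene with a replicated peak, and Ckm (4.59%) the liver and muscle lineage gene. Foxc1 and Slc1a2 had no peak in replicate 1's own list. Tek had 0.300% in replicate 1 and 1.64% in replicate 2, and Ckm 1.81% and 2.79%.

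Chromosome 7, which holds large clusters of zinc finger and vomeronasal receptor genes, had the highest share of its sequence in replicated peaks. It reached 1.88%, followed by chromosome 17 with 1.47%, chromosome 4 with 1.01%, chromosome 18 with 0.981% and chromosome 13 with 0.952%. The X chromosome had 0.186% and the Y chromosome 0.00802%, with 8 peaks. As the sexes were pooled, X and Y had fewer copies than the autosomes, and mappability was not tested. Their shares are thus not directly comparable with those of autosomes. Chromosome 7 ranked highest and chromosome X second lowest in each replicate's own list too, at 1.39% and 1.84% for chromosome 7 and 0.242% and 0.396% for the X. No test was run between chromosomes.

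**Figure D4:**
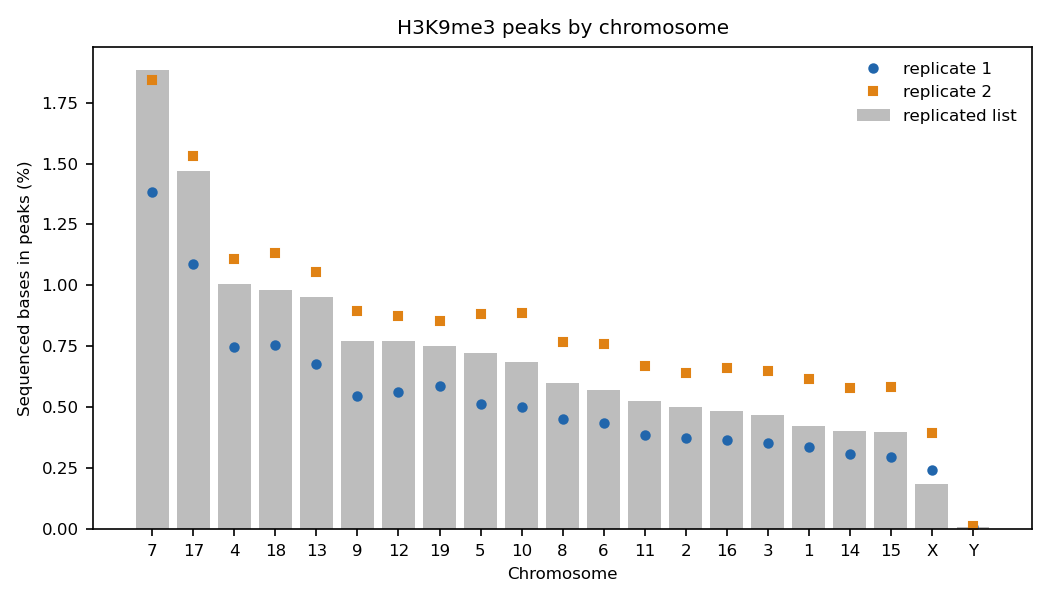
Percent of each chromosome's sequenced bases in H3K9me3 peaks, with bars for the replicated list and points for both replicates, ordered by the replicated list. Values ran from 1.88% on chromosome 7 to 0.00802% on chromosome Y. With the sexes pooled, X and Y had fewer copies than the autosomes.

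Exons and intergenic sequence held more of the replicated peaks than their rotated share, and introns less. Exons held 8.53% of peak base pairs against 5.35% ± 0.355 on rotation and introns 33.3% against 43.2% ± 1.66 (permutation test, adjusted p = 0.0005 for both). Intergenic sequence held 58.2% against 51.4% ± 1.76 (permutation test, adjusted p = 0.000667), a call that ended among the 50% of peaks of highest −log10 q, where the adjusted permutation p was 0.0815. Promoters of protein-coding genes held 2.07% against 1.75% ± 0.182 (permutation test, adjusted p = 0.116), a direction that turned in replicate 2 (0.996-fold) and in the pooled list (0.984-fold). The promoter share passed the threshold in replicate 1's own list (1.23-fold), among the 50% of peaks of highest −log10 q (1.39-fold) and with the peaks found in both replicates (1.32-fold), with adjusted permutation p from 0.0103 to 0.0358. The 5 Mb next to the centromeric gap held 4.79% against 4.04% ± 1.43 (permutation test, adjusted p = 0.524). CpG sites were depleted in the peaks, with an observed to expected ratio of 0.162 against 0.193 ± 0.00285 on rotation. Soft-masked repeat sequence made up 28.6% of peak base pairs against 33.9% ± 0.740. For both the permutation test gave an adjusted p of 0.003, from 0.002, the smallest that 1000 rotations can give. Rotation also places peaks on repeats where reads may not map, and mappability was not tested. The lower repeat share thus does not show that the mark avoids repeats. The GC content was 42.5% against 42.1% ± 0.267 (permutation test, adjusted p = 0.0979), and it passed the threshold in each replicate's own list and in the pooled list.

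The protocadherin and zinc finger genes above were covered in both replicates, but the replicates' peak lists overlapped only in part. Replicate 1 had 41272 peaks (median width 260 bp) over 13.5 Mb, and replicate 2 had 67132 (255 bp) over 21.8 Mb. They shared 5.97 Mb, 43.0-fold the rotated mean of 0.139 ± 0.0309 Mb (two-sided rotation permutation test, p = 0.0002, the smallest that 10000 rotations can give). Of replicate 1's peaks 39.0% were covered by at least 50% of their length in replicate 2, with an exact binomial 95% interval from 38.5% to 39.4%. Of replicate 2's peaks 21.5% were covered in replicate 1 (21.1% to 21.8%). These intervals treat clustered peaks as independent, so they are too narrow, and they do not measure variation between replicates. Across 21369 overlapping peaks, which are not independent replicates, Spearman's rho of the signal values was 0.192.

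The replicated list held 30344 peaks with a median width of 476 bp, covering 18.1 Mb or 0.682% of the sequenced bases. All of them were in the pooled list of 84458 peaks, of which 35.9% were kept. Kept peaks were wider than those not kept (median 476 against 238 bp), with a higher median signal value (3.55 against 2.68) and −log10 q (4.16 against 2.01). Of the replicated peaks 61.9% were overlapped by at least 50%, of either peak, by peaks of both replicates, and 11340 had no overlap with the list of at least 1 replicate. In zinc finger genes, the difference between the 3′ and the 5′ part was 7.75 percentage points with only the peaks found in both replicates.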

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

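The test of the signal rank of the peaks with the highest −log10 q was chosen only after the result was seen. After the values were seen, the counts of these peaks were also judged by an exact interval rather than by the plain majority first set. The rule for reads shared between tandem copies was also widened then. A low share of repeated stretches of 31 bases (31-mers) was allowed to decide it alone. By the rule first set, a comparison with 3 tandem families, it was undecided.

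Replicated peaks also lay outside the sequence used for the comparisons: 219 were on 21 contigs not placed in chromosomes 1 to 19, X and Y, 59 of them on a single contig. A signal in sequence left out of the tests is what drew attention to them. Their median −log10 q was 15.8 against 4.16 on the chromosomes, and their median signal value 4.26 against 3.55. No biological explanation was tested, and without control reads an artefact of unplaced repeats stays open. Of the 20 replicated peaks of highest −log10 q, 8 lay on these contigs.

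These 20 peaks may reflect sequence with high read depth in both ChIP and control, where a small enrichment reaches a very high −log10 q. Such peaks would mostly rank low by signal value. Of the 20, 9 were in the top 1% by signal value (exact 95% interval 23.1% to 68.5%), and 10 of the 20 highest on chromosomes (27.2% to 72.8%). Both counts lie near 50%, and some of these peaks are neighbours on 1 stretch, so that the intervals are too narrow. This leaves the explanation open for the 20 as a set, but single peaks differed. On chromosome 17, neighbouring peaks with −log10 q of 110 and 81.9 ranked 28791 and 29970 by signal value among 30344 replicated peaks. The peak over Klf14, with a −log10 q of 115, ranked 1. Of the 20 highest on chromosomes, 2 had over 50% of their 31-mers repeated in the assembled genome (exact 95% interval 1.23% to 31.7%), so most of them were not made mostly of repeated 31-mers. Repeated 31-mers were still more frequent there, with a mean of 25.7% against 6.16% over all replicated peaks, and a part played by partly repeated sequence stays open. Sequence whose copies are missing from the assembly was not tested.

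Zinc finger genes carried replicated peaks in 164 of 417 genes. Gene length alone does not account for this, with a fold of 3.30 over length-matched random lists. Nor does the soft-masked percent of the gene body alone, with 2.15 over lists matched on it. Lists matched on both together were not drawn, and single kinds of repeat and flanking sequence were not tested. Reads shared between identical copies would need repeated sequence inside the peaks, but a mean of 8.59% of 31-mers there occurred more than once (mean plus 2 standard errors 10.4%). The share was 22.9% in the rest of the same genes and 6.16% inside all replicated peaks. It was also lower inside than outside the peaks in protocadherin, olfactory, vomeronasal and imprinted genes. How reads with several matches were handled is not known, and if they were dropped, a low share was given in advance. Reads placed wrongly between similar but not identical copies were not tested. The comparison with 3 tandem families was undecided by itself: the zinc finger fold exceeded theirs by 0.412, between the summed rotation SD of 0.314 and 2 times that, 0.628. Copies missing from the assembly remain open, and no biological explanation was tested, since all samples belong to 1 group.

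Replicate 2's list was longer than replicate 1's, 67132 against 41272 peaks. Its unshared peaks were weaker, with a median −log10 q of 1.64 against 2.27 for shared ones, which is consistent with more weak peaks being called in replicate 2. In replicate 1 the unshared peaks were weaker too (1.38 against 2.29). The share of peaks with q under 0.05 was 59.3% in replicate 2 against 75.4% in replicate 1, so more of replicate 2's list was weak. Replicate 2 also had more peaks with q under 0.05 (39817 against 31120). The median −log10 q of its unshared peaks was itself past that bound. This count thus cannot show whether weak calls account for the whole difference. Zinc finger genes were still at 1.54-fold the rotated mean among the unshared peaks, so these did not lie wholly outside the genes called in the main list, although the lists past the threshold were not all the same as in the main list: olfactory receptors were called above the rotated mean (adjusted permutation p = 0.0409) and Zbtb and ribosomal protein genes below it (adjusted permutation p = 0.0232 for both), and the germline call was lost (0.858-fold). The sequence composition of these peaks, the depth and the number of embryos, 34 against 24, were not tested and stay open.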

How the results depend on the processing

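No paired analysis was possible because both samples belong to 1 group. Random lists matched on soft-masked percent and the peaks found in both replicates were chosen after the data were seen. Calls against random lists ignore the clustering of genes, and the lists matched on soft-masked percent were not matched on length. Of 215 values that answer a comparison under an alternative, 182 kept their direction and their side of the threshold, or their size, and 33 did not; except where the list or rule itself sets the size, the cause was not tested. The gene-body calls of C2H2 zinc finger, protocadherin, vomeronasal and imprinted genes, the promoter calls of protocadherin, imprinted and germline genes and the position within zinc finger genes passed under each alternative run for them. Germline gene bodies lost their call without either replicate (1.27- to 1.48-fold), in the pooled list (1.28-fold), on the autosomes (1.67-fold), with at least 500 bp (1.72-fold) and with 10 kb added (1.60-fold), and vomeronasal promoters lost it in the 50% of peaks of highest −log10 q (2.94-fold). Other tandem clusters gained a call in gene bodies without replicate 2 (1.65-fold) and against length-matched lists (1.84-fold). Gene lists called below chance, 0 in the main analysis, numbered 2 to 4 without either replicate, 4 in the pooled list (ribosomal protein, Zbtb, microglial and neuronal genes), 1 with 10 kb added (ribosomal protein genes) and 2 against lists matched on soft-masked percent (olfactory receptors and ribosomal protein genes), and in promoters 1 in the pooled list (ribosomal protein genes). The share of peaks in promoters of all coding genes ran from 0.996- to 1.23-fold without either replicate, the latter past the threshold, fell to 0.984-fold in the pooled list, and passed in the 50% of peaks of highest −log10 q (1.39-fold) and with the peaks found in both replicates (1.32-fold). Intergenic sequence lost its call in the 50% of highest −log10 q (1.07-fold), and GC content gained one without either replicate (both 1.02-fold) and in the pooled list (1.02-fold). The 50% of highest −log10 q covered 0.417% of the sequenced bases. The share of replicate 1's peaks found in replicate 2 was 31.7% at equal list length, 39.8% on the autosomes, 51.6% with a 1 bp overlap and 25.9% with a reciprocal one; for replicate 2 these were 27.1%, 21.9%, 31.5% and 15.9%, and 20.0% in the 50% of highest −log10 q. Spearman's rho was 0.253 with −log10 q in place of the signal value. Folds that crossed 1 belonged, in gene bodies, to olfactory receptors (0.717, soft-mask matched), Hox genes (0.377 to 1.35 without either replicate, 1.16 pooled), hindbrain transcription factors (1.02 with 10 kb added), neuronal genes (0.860 to 1.204 without either replicate, 1.54 soft-mask matched), erythroid genes (0.738 to 1.15 without either replicate) and endothelial genes (1.08 length-matched, 1.74 soft-mask matched). In promoters they belonged to Zbtb genes (1.62 in the 50% of highest −log10 q, 1.35 in both replicates, 1.41 length-matched, 1.32 soft-mask matched), Hox genes (1.14 to 1.30 without either replicate, 1.58 pooled), hindbrain transcription factors (0.872 to 1.47 without either replicate, 0.854 autosomes, 0 in the 50% of highest −log10 q and in both replicates), erythroid genes (0 to 1.16 without either replicate) and histone genes (0 to 0.593 without either replicate, 0.489 pooled, 0 in the 50% of highest −log10 q and in both replicates, 0.584 at 2.5 kb, 0.799 length-matched, 0.990 soft-mask matched). Except for the olfactory receptors, none of these folds had an adjusted p under 0.05, and most rest on 1 or a few genes. Of 308 values for 77 named genes, 165 stayed within the SD of the replicates and 143 moved beyond it. Depth is unknown here, so its effect was not tested.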

Other observations

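The hypothesis on dense windows was set before its test was run, and the symbol families were chosen only after the gene list results were seen. Genes named here were chosen after their values were seen.

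Among 1 Mb windows, the protocadherin window of chromosome 18 had the most sequence in replicated peaks, with 34.1%, followed by a window of chromosome 12 with 26.2%, which held 48 immunoglobulin variable genes and no protein-coding gene. Then came windows with Ceacam and Psg genes on chromosome 7 (23.4%), placental cathepsins such as Cts3 and Cts7 on chromosome 13 (20.4%), and Vmn1r66 and Zscan4c on chromosome 7 (19.3%). Skint5 and Skint6 on chromosome 4 had 17.8% and the Scgb genes of chromosome 7 17.2%. Whether tandem families other than zinc finger genes are over-represented in such windows was not tested. A candidate explanation, that dense windows are zinc finger gene clusters, was tested: 4 of the 20 densest windows held at least 3 zinc finger genes, against 0.894 ± 1.01 on rotation (rotation permutation test, p = 0.04). Clusters of genes with Zfp, Zscan or Zkscan symbols were thus more frequent than on rotation, and 16 of the 20 windows held fewer than 3 such genes. Zinc finger genes under other symbols were not counted, so how many of the dense windows are zinc finger clusters stays open.

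To look for further families, 329 groups of at least 8 protein-coding genes with a shared symbol stem were tested in gene bodies and in promoters. None passed an adjusted p of 0.05 in the rotation permutation test, while 21 in gene bodies and 6 in promoters had an unadjusted permutation p under 0.05, and the lowest, for Tmem genes with peaks in 21 of 241 bodies (0.547-fold), had an adjusted permutation p of 0.112 and an unadjusted one of 0.00034.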
